A study of Mus musculus with 6 samples.

How the data were processed

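RNA from BL185, M1 and I1 cells, grown in the same serum-containing medium and extracted with Trizol, per the labels' protocols, was labelled with a 3′ IVT kit and hybridised to 6 Affymetrix mouse arrays, 2 per line. The authors deposited 1 log2 value per probe set and array, which per the submitters' processing notes came from RMA and the affy package. The versions, the background correction, the normalization settings and the chip definition are not given in the sources used here. That the deposited values are log2 was read from their range, 5.80 to 15.4. The columns differed in distribution, with SDs from 1.62 to 1.97, so the arrays had not been brought to a single distribution at the probe set level. No detection calls were used, and dim genes cannot be told from background. The number of arrays limits the precision of every value.

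Of 45101 probe sets, 34945 named 1 gene in the platform annotation, 932 named several, 64 were Affymetrix controls and 9160 others named none. Of the 1-gene probe sets, 34741 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 18193 genes, 9010 of them with more than 1 probe set. Genes of the fixed lists without a probe set naming them alone were not analysed here. The number of unused columns of sample values was 0.

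Groups and replicate numbers were taken from the sample titles. Before the data were examined, the design, the tests, 27 gene lists, the rule for named genes and most alternatives were fixed. limma 3.58.1 in R 4.3.3 fitted a mean per line to all 6 arrays (3 residual degrees of freedom, 2.27 prior degrees of freedom), and the 3 contrasts M1 minus BL185, I1 minus BL185 and I1 minus M1 were tested with eBayes. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. Errors given with log2 changes are SEs of this fit, which pools the spread over all lines. Because the M1 arrays differed most from each other, the pooled spread is set largely by M1, and counts without M1 replicate 1 are given beside the main ones. With that array left out, M1 is a single array assumed to vary like the other lines, 2 residual degrees of freedom remain, and small level-dependent shifts between lines also pass the test.

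Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all 81 tests, with an estimated correlation and fry as alternatives. fry's mixed test, which takes changes in either direction, called 14 lists in M1, 17 in I1 and 0 between the selected lines. Members were also counted after adjustment over the list alone. Named genes were, per contrast, the 8 with the largest rise and the 8 with the largest fall among called genes whose 2 lines' arrays did not overlap and whose higher mean was at least 6. To these were added up to 4 called members per list, 6 genes per direction called the same way in both selected lines, and 18 markers whatever they showed. With fewer than 10 calls, the 8 genes per direction with the smallest p were named. A gene whose other probe sets disagreed at an unadjusted p under 0.05 is named with that disagreement.

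The shared BL185 arrays were allowed for with 100 simulations of unchanged groups. In data simulated for I1 minus BL185 (18193 genes, 200 changed, each line's measured spread), the fit recovered 0% of changes of 1 log2 unit, 43.3% of changes of 2 and 83.3% of changes of 4, with 0 false calls among 84. With BL185's spread in every line it recovered 100% at each size, with 12 false calls among 212. Level-matched comparisons used 10000 random lists drawn from 50 bins of mean signal, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

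The other settings fixed in advance were a minimum mean log2 of 5, the mean of a gene's probe sets, every probe set, cyclic loess, median centring, 50 added to the linear value, eBayes with trend or robust, the replicate number as a block, only the arrays of the lines compared, adjustment over 3 contrasts, an adjusted p of 0.01, a change of at least 1, and each array left out. Added after the data were seen were a minimum mean log2 of 8, array weights, quantile normalization, the 18S control as a covariate, crossed replicate numbers and the fuller counts without M1 replicate 1.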

Results

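Gene expression was measured on 6 Affymetrix mouse arrays in 3 related lines of hepatocellular carcinoma cells. BL185 is the parent line. M1 and I1 are subpopulations of it that had been selected for their ability to migrate, and the sample titles call each a subclone line. A subclone without this selection was not measured, so a difference from BL185 cannot be credited to the selection itself. Each line was measured on 2 arrays, and the question was how expression in each selected line differed from that of the parent. The labels do not say whether the 2 arrays of a line came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. After reduction to 1 probe set per gene, 18193 genes were tested.

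The arrays were not equally alike within the lines. Across all probe sets, which are not independent replicates, the 2 BL185 arrays correlated at r = 0.997 and the 2 I1 arrays at 0.994, whereas the 2 M1 arrays correlated at 0.911. Over the genes tested, the between-replicate SD was 0.10 log2 units in BL185, 0.16 in I1 and 0.65 in M1. M1 replicate 1 had the narrowest range of signals, with an SD of 1.62 over probe sets against 1.94 on M1 replicate 2, 1.97 and 1.95 on the BL185 arrays and 1.83 and 1.88 on the I1 arrays. Above a log2 signal of 12 lay 1797 of its probe sets, 3270 on M1 replicate 2, 3317 and 3256 on the BL185 arrays and 2629 and 2988 on the I1 arrays. The I1 arrays were thus also narrower in range than those of the parent. The control probe set for the 3′ part of 18S ribosomal RNA read 10.13 ± 0.02 in BL185, 11.59 ± 1.28 in M1 and 11.39 ± 0.17 in I1 (SD, n = 2), and stood at 12.50 on M1 replicate 1. The 3′ minus 5′ signal of Actb, a measure of RNA integrity, was 0.98 ± 0.14 in BL185, 1.34 ± 0.14 in M1 and 1.45 ± 0.03 in I1 (SD, n = 2), although its 3′ probe set lay 0.174 to 0.352 below the highest value of each array, where differences are squeezed. The array medians lay between 7.87 and 8.11, and for a gene whose mean in either line of a comparison was about that or lower, where signal cannot be told from background, the size of a change is not exact. The 3′ minus 5′ value of the added poly-A controls, which are not RNA of the cells, was 2.12 and 1.93 in BL185, 1.48 and 2.75 in M1 and 2.72 and 3.18 in I1. A 3′ minus 5′ difference therefore cannot be read as RNA integrity alone. The means of the 3′ 18S and Actb measures were higher in both selected lines, and every gene and list difference from BL185 given here stands beside them.

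**Figure D1:**
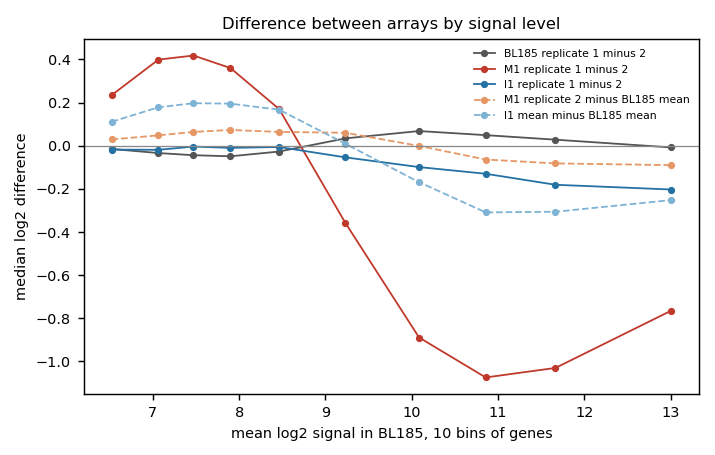
Median log2 difference between arrays (vertical axis) in 10 bins of genes ordered by their mean log2 signal in BL185 (horizontal axis); solid lines compare the 2 replicates of a line, and dashed lines compare M1 replicate 2 and the I1 mean with the BL185 mean. M1 replicate 1 read 0.42 above replicate 2 in the bin around 7.47 and 1.07 below it in the bin around 10.86, whereas BL185 replicates differed by at most 0.07 in any bin.

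In M1, the largest rises among called genes were in Ndnf, a secreted neurotrophic factor (log2 change 4.46 ± 0.51, SE), Ccl2, a monocyte-attracting chemokine (4.09 ± 0.31), Fstl1, a secreted glycoprotein of the follistatin family (mean log2 signal from 7.93 ± 0.17 to 11.94 ± 0.78; SD, n = 2), Gxylt2, a xylosyltransferase that acts on Notch (3.71 ± 0.32), and the Wnt ligand Wnt10a (3.63 ± 0.41). The proliferation marker Mki67 (3.37), the mitotic regulator Cdca3 (3.29) and the replication factor Pclaf (3.20) followed. The largest falls among called genes were in Clca4a, of the chloride channel regulator family, whose mean log2 signal went from 13.93 ± 0.07 to 8.30 ± 0.18 (SD, n = 2), in the neuropeptide gene Vip (−5.43), in the MYC family transcription factor Mycn (−4.22), in the EGF receptor ligand Ereg (−4.10), in Dynap (−4.01), in the zinc importer Slc39a4 (−3.91), in the retinaldehyde dehydrogenase Aldh1a3 (−3.76) and in the glycosyltransferase B4galnt2 (−3.75). The Mycn values in BL185, 15.36 and 15.43, were the highest on those arrays, so the size of its fall is not exact. Of its 2 other probe sets, both near the array medians, 1 differed in direction (0.70) and neither showed the high BL185 signal. The means of Ndnf (7.63), Ccl2 (7.86) and Fstl1 in BL185 and of Aldh1a3, Slc39a4 and Vip in M1 (6.93 to 7.77) lay near or below the array medians of 7.87 to 8.11, where signal cannot be told from background, so these sizes are not exact either.

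By limma with Benjamini-Hochberg adjustment, 160 of 18193 genes passed an adjusted p of 0.05 in M1 against BL185, 50 higher and 110 lower. The smallest called change was 2.48-fold. All 160 kept their direction whichever BL185 or M1 array was left out, which is little of a test for changes selected as this large. Leaving out an I1 array cannot alter these changes. Without M1 replicate 1 the count was 4369, of which 689 were higher and 594 lower by at least 2-fold, and all 160 were among the 4369 in the same direction. It was 12879 without M1 replicate 2, and 0 without either BL185 array or either I1 array. The share of calls that were higher was 31.2% as deposited, 46.0% after cyclic loess, 52.6% after quantile normalization and 67.7% with the 18S value as a covariate. The slope of that covariate is set mainly by the M1 arrays, whose 18S values differed by 1.82, against 0.24 in I1 and 0.02 in BL185.

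The cell cycle list moved the furthest in M1. All 40 measured members had a positive mean change with a median of 1.67 (camera, adjusted p = 7.38e-23, and 0.725 with an estimated correlation). Of these 7 rose and 0 fell over all genes, and 31 rose when adjusted over the list alone. Mki67, the thymidine kinase Tk1 (2.92 ± 0.26), the mitotic survival factor Birc5 (2.92 ± 0.26) and the replicative helicase subunit Mcm5 (2.65 ± 0.26) were the largest among those called over all genes. With M1 replicate 1 left out all 40 were called higher, with a median of 2.08. The Wnt list was also higher (median 0.42, camera adjusted p = 0.0019, and 0.725 with an estimated correlation). Its median was 0.22 without M1 replicate 1, and its adjusted p 0.0558 without M1 replicate 2. Of the list, 3 of its 42 members rose, 4 when adjusted over the list alone, where 1 fell. These were the ligands Wnt10a and Wnt4 (2.86 ± 0.31) and Axin2 (2.30 ± 0.28), a feedback target of beta-catenin. Of 31 mesenchymal genes 3 rose and 0 fell (4 and 2 when adjusted over the list alone; median 0.23, camera adjusted p = 0.0368, 0.725 with an estimated correlation and 0.0741 without M1 replicate 2). They were the calcium-binding protein S100a4 (2.38 ± 0.29), the matrix protein Sparc (2.18 ± 0.22) and the transcription factor Twist2 (1.68 ± 0.17).

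The unfolded protein and integrated stress response list was lower in M1 (median −0.92, camera adjusted p = 1.82e-10, and 0.725 with an estimated correlation), with a median of −0.44 without M1 replicate 1. Of its 36 members 4 fell and 0 rose, and 17 fell when adjusted over the list alone. The phosphatase subunit Ppp1r15a (−3.46 ± 0.25), the transcription factor Ddit3 (−2.94 ± 0.18), the pseudokinase Trib3 (−2.62 ± 0.24) and the lipoprotein receptor Vldlr (−1.94 ± 0.24) were those called. The hypoxia and glycolysis list had a median of −0.99 (camera adjusted p = 1.62e-08, and 0.725 with an estimated correlation), or −0.60 without M1 replicate 1, with 1 of 35 members lower, the aldolase Aldoc (−1.96 ± 0.22), and 16 lower when adjusted over the list alone. The p53 target list had the same median (camera adjusted p = 7.58e-06, and 0.725 with an estimated correlation), or −0.47 without M1 replicate 1, with 0 of 25 called over all genes, and 10 lower and 1 higher when adjusted over the list alone. Smaller shifts passed camera for fatty acid and lipid metabolism (median −0.22, adjusted p = 0.0368), NRF2 and glutathione genes (−0.30, 0.0388) and interferon response genes (−0.25, 0.0456). With an estimated correlation their adjusted p was 0.818, 0.838 and 0.725. Of 10000 random lists matched on signal, a comparison chosen after the values were seen, 1610, 1142 and 2 had medians as low. Lipoprotein lipase, Lpl (−2.32 ± 0.27), was the called member of the first of these, and over the list alone 3 fell and 1 rose there, 4 fell in the NRF2 list and 6 fell in the interferon list. The camera call was lost without BL185 replicate 1 for fatty acid (adjusted p = 0.0547) and NRF2 genes (0.079) and without M1 replicate 2 for fatty acid genes (0.0586). For interferon genes it was lost without M1 replicate 2 (0.44), BL185 replicate 2 (0.0616; median −0.14) or either I1 array (0.0549). The fatty acid and NRF2 medians were −0.05 and −0.04 without M1 replicate 1 and −0.60 each without M1 replicate 2.

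Hepatocyte genes had a median of 0.39 in M1 (camera adjusted p = 0.0388, and 0.725 with an estimated correlation) although the called member, the fibrinogen chain Fgb, fell, to an M1 mean of 7.70 that leaves its size (−1.78 ± 0.22) not exact. Stellate cell and fibroblast markers (median 0.37, adjusted p = 0.00768) and endothelial markers (0.33, 0.0184), with 0.812 and 0.725 at an estimated correlation, had 0 of 20 members called each, over all genes or over the list alone. For these 3 lists 19, 406 and 579 of 10000 lists matched on signal had medians as high. With M1 replicate 1 left out their medians were 0.11, 0.03 and 0.11 and their camera adjusted p 0.287, 0.593 and 0.341, and that of the fatty acid and NRF2 lists 0.463 and 0.491. Leaving out BL185 replicate 1 gave an adjusted p of 0.0621 for hepatocyte genes, and leaving out M1 replicate 2 a median of 0.65 for stellate markers. None of the 12 lists that passed camera in M1 did so with an estimated correlation, where the smallest adjusted p was 0.725, and fry called 0 lists in 1 direction. That estimate rests on 3 residual degrees of freedom with a spread set largely by M1. Camera tests as unlike as collagen genes in I1 (unadjusted p = 0.0391) and cell cycle genes in M1 (0.122) shared the adjusted 0.725. A call lost there does not show that a list was unchanged.

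The other lists did not pass camera in M1. The adjusted p was 0.0502 for collagen and basement membrane genes, of which 2 of 38 rose (4 rose and 2 fell when adjusted over the list alone), the fibrillar collagen chain Col5a1 (2.94 ± 0.22, a size not exact with a BL185 mean of 7.965) and the microfibrillar chain Col6a2 (2.71 ± 0.25). It was 0.268 for TGF-beta genes (2 of 37 higher, and 6 higher and 2 lower over the list alone, with Fstl1 and the ligand Tgfb3, 1.95 ± 0.24), where it was 0.00572 without M1 replicate 1 with 15 higher and 7 lower. It was 0.783 for extracellular proteases and inhibitors (1 of 36 higher, and 1 higher and 3 lower over the list alone, with the metalloproteinase inhibitor Timp1, 1.83 ± 0.23). For chemokines and cytokines it was 0.174, with Ccl2 the called member of 38, and 4 higher and 4 lower over the list alone. For receptor tyrosine kinases and ligands it was 0.29, with Ereg the called member of 47, over all genes and over the list alone. It was 0.781 for actin cytoskeleton and motility genes, where the capping protein Capg fell (−3.60 ± 0.32; 3 higher and 1 lower over the list alone), 0.785 for epithelial junction and keratin genes and 0.726 for integrins and adhesion genes, each with 0 members called over all genes or the list alone. It was 0.908 for fetal liver and progenitor genes, where Prom1 (−2.93 ± 0.21) and the ductal transcription factor Sox9 (−2.06 ± 0.22) fell (1 higher and 3 lower over the list alone), and 0.109 for macrophage and leukocyte markers, where Cd68 (−3.21 ± 0.21) and Cd53 (−1.66 ± 0.21) fell, to M1 means of 7.44 and 7.97 that leave the sizes not exact, 2 over the list alone as well. For cholesterol biosynthesis and Hedgehog genes, with 0 members called, it was 0.163 and 0.642. It was 0.547 for Notch genes (Sox9 lower; 1 higher and 2 lower over the list alone), 0.277 for YAP targets (Birc5 higher; 2 higher and 4 lower over the list alone) and 0.61 for imprinted and germline genes, where Phlda2 fell (−1.37 ± 0.17; 2 lower over the list alone).

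In I1, Fstl1 rose from 7.93 ± 0.17 to 12.62 ± 0.20 in mean log2 signal (SD, n = 2). Krt14, a keratin of basal epithelium (log2 change 4.27 ± 0.23, SE), S100a4 (3.42 ± 0.29), Gxylt2 (3.40 ± 0.32), Cdca3 (3.28 ± 0.33), Col6a2 (3.26 ± 0.25), the microtubule regulator Stmn2 (3.07 ± 0.29) and Pclaf (3.00 ± 0.23) also rose. Clca4a (−5.61 ± 0.21), Mycn (−4.46 ± 0.17), Dmrta1 (−3.79 ± 0.16), Aldh1a3 (−3.55 ± 0.21), the secreted carbonic anhydrase Car6 (−3.42 ± 0.32), Vip (−3.35 ± 0.23), Bcl2l15 (−3.32 ± 0.21) and Trim15 (−3.30 ± 0.17) fell. For Mycn, whose BL185 values were at the top of the arrays, the size of the fall is not exact, and 1 of the 2 other probe sets near the array medians differed in direction here too (0.65). The sizes for Fstl1 and Krt14, with BL185 means of 7.93 and 7.59, and for Dmrta1, Aldh1a3 and Trim15, with I1 means of 6.29, 7.14 and 7.41, are not exact either, as these means lay near or below the array medians.

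By limma, 93 genes passed an adjusted p of 0.05 in I1 against BL185, 35 higher and 58 lower. The smallest called change was 2.89-fold. All 93 kept their direction whichever BL185 or I1 array was left out, which is again little of a test, and leaving out an M1 array cannot alter these changes. The count was 8481 without either M1 array, of which 446 were higher and 1058 lower by at least 2-fold once M1 replicate 1 was left out, and all 93 were among these 8481 in the same direction. It was 0 without either BL185 array or either I1 array. The share of calls that were higher was 37.6% as deposited, 48.4% after cyclic loess, 59.1% after quantile normalization and 69.6% with the 18S covariate.

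The cell cycle list again moved the furthest. In I1, 39 of 40 members had a positive change, with a median of 1.50 (camera adjusted p = 6.68e-24, and 0.725 with an estimated correlation), 5 rose over all genes and 30 when adjusted over the list alone, and 0 fell. Tk1 and Birc5 (each 2.69 ± 0.26), Mcm5 (2.25 ± 0.26) and the mitotic activator Cdc20 (2.16 ± 0.19) were the largest among those called over all genes. The unfolded protein and integrated stress response list was lower (median −0.87, camera adjusted p = 6.59e-11, and 0.725 with an estimated correlation), with Ppp1r15a (−3.07 ± 0.25), Ddit3 (−2.45 ± 0.18) and Trib3 (−2.15 ± 0.24) called among 36 members, and 13 lower when adjusted over the list alone. The p53 target list had a median of −0.45 (camera adjusted p = 0.001, and 0.8 with an estimated correlation), with 0 of 25 called over all genes and 8 lower and 1 higher over the list alone. Collagen and basement membrane genes were higher (median 0.24, camera adjusted p = 0.00205, and 0.725 with an estimated correlation), with Col6a2 and Col5a1 (2.53 ± 0.22, a size not exact with a BL185 mean of 7.965) called among 38 and 4 higher over the list alone. Mesenchymal genes were also higher (0.21, 0.0161, and 0.725 with an estimated correlation), with S100a4 and Sparc (2.16 ± 0.22) called among 31, and 5 higher and 1 lower over the list alone.

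Cholesterol biosynthesis genes (median 0.47, camera adjusted p = 0.00394, and 0.838 with an estimated correlation) had 0 of 20 members called over all genes or over the list alone. Wnt genes (0.29, 0.00394, and 0.725 with that estimate) had 0 of 42 called over all genes and 2 higher over the list alone. TGF-beta genes (0.20, 0.0388, and 0.838 with that estimate) had Fstl1 called among 37, with 7 higher and 1 lower over the list alone. Hypoxia and glycolysis genes (−0.13, 0.0388) and interferon genes (−0.08, 0.0353) had 0 called over all genes, and 0 and 2 lower over their lists alone. With an estimated correlation their adjusted p was 0.838 and 0.725, and 1736 and 66 of 10000 lists matched on signal had medians as low. Their medians were −0.08 and −0.13 without BL185 replicate 2 and −0.26 and −0.17 without I1 replicate 2, and that of TGF-beta genes was 0.10 without BL185 replicate 1. None of the 10 lists passed with an estimated correlation (adjusted p = 0.725 or higher), and fry called 0 in 1 direction. Without M1 replicate 1 and without M1 replicate 2 the camera adjusted p was 0.0886 and 0.0709 for TGF-beta genes and 0.105 and 0.0902 for interferon genes. Leaving out I1 replicate 1 gave 0.0555 for interferon and 0.082 for hypoxia genes. Outside these lists, Timp1 (2.07 ± 0.23) and Ccl2 (2.82 ± 0.31) rose, and Cd68 (−3.05 ± 0.21) and Prom1 (−2.74 ± 0.21) fell. The sizes for Ccl2 and Cd68 are not exact, with a BL185 mean of 7.86 and an I1 mean of 7.60. Camera did not call the hepatocyte (adjusted p = 0.109), stellate (0.0534), endothelial (0.109) or macrophage (0.205) lists in I1, nor the epithelial (0.149), integrin (0.369), actin (0.429), chemokine (0.149), receptor tyrosine kinase (0.298), protease (0.369), fetal liver (0.769), Hedgehog (0.783), Notch (0.905), YAP (0.248), imprinted (0.783), fatty acid (0.905) or NRF2 (0.623) lists. Of these, hepatocyte genes (0.0383) and stellate markers (0.047) passed camera without M1 replicate 1.

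**Figure D2:**
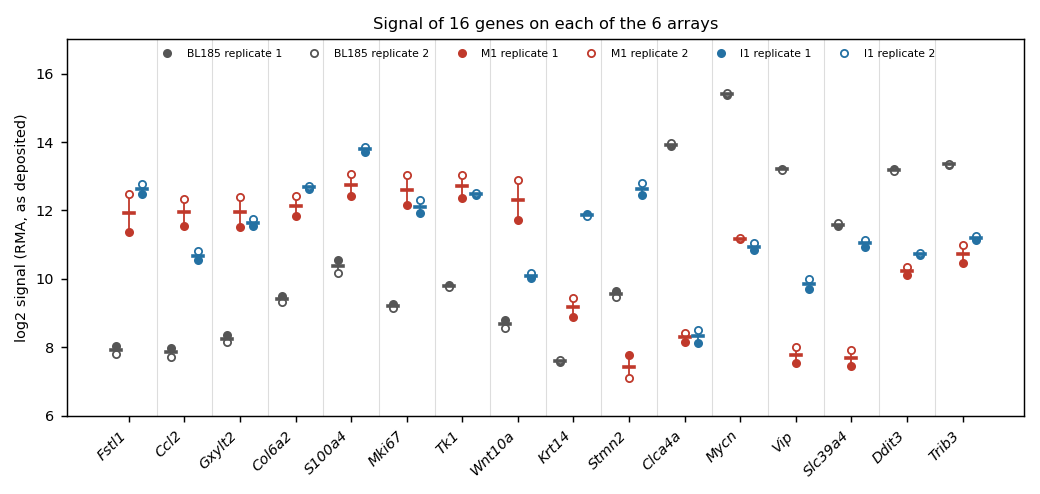
Log2 signal as deposited (vertical axis) of 16 genes on each of the 6 arrays, with filled circles for replicate 1, open circles for replicate 2, a bar at the mean of each line and a thin line joining its replicates. Clca4a had means of 13.93 in BL185, 8.30 in M1 and 8.32 in I1, while Stmn2 had means of 9.55, 7.43 and 12.62.

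Genes changed together in both selected lines. Of the calls against BL185, 18 genes were higher in both M1 and I1, 51 were lower in both and 0 went opposite ways. Among the genes higher in both were Fstl1, Gxylt2, Cdca3, Pclaf, Ccl2 and Col6a2, and among those lower in both were Clca4a, Mycn, Dmrta1 (M1 mean 6.32), Aldh1a3, Car6 (M1 mean 8.05) and Vip, with sizes that are not exact. Independent lists of these sizes would share 0.0962 higher and 0.351 lower genes. In 100 simulations of unchanged groups against the shared BL185 arrays the shared calls were 0, with a highest value of 0, which says little since a simulated M1 had at most 1 call and a simulated I1 had 0. Across genes the log2 changes of M1 and I1 correlated at r = 0.882 (rho 0.87) against a simulated mean r of 0.084, and their covariance was 0.362 against a simulated 0.00517, a difference of 0.357. The simulated groups were unchanged and so carried no level-dependent shift. In bright minus dim bins of parent signal, the change from BL185 was −0.45 in I1 and −0.13 in M1 replicate 2. M1 replicate 1 minus replicate 2 was −1.31 in this measure. Such a shift in both lines would also make their changes correlate. Cyclic loess, which levels such differences between arrays, and quantile normalization gave 1191 and 735 shared calls, so the shared calls were not lost with them. The median SE also fell, from 0.27 to 0.17 and 0.18, so these counts do not measure the part of the shift. Its part in r, the covariance and the shared calls was thus not measured. With a different single BL185 array as the control of each line, so that none was shared, r was 0.846 and 0.872 and the covariance 0.353 and 0.36. Fits with a single BL185 array left no calls to compare in this way, so part of the excess of shared calls may come from the shared controls. With M1 replicate 1 left out, 1382 genes were higher in both (479.9 for independent lists), 2014 were lower in both (539.3) and 81 went opposite ways, with r = 0.768 and a covariance of 0.25. The shared count was 7136, with r = 0.784, without M1 replicate 2 and 0 without either BL185 or either I1 array.

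**Figure D3:**
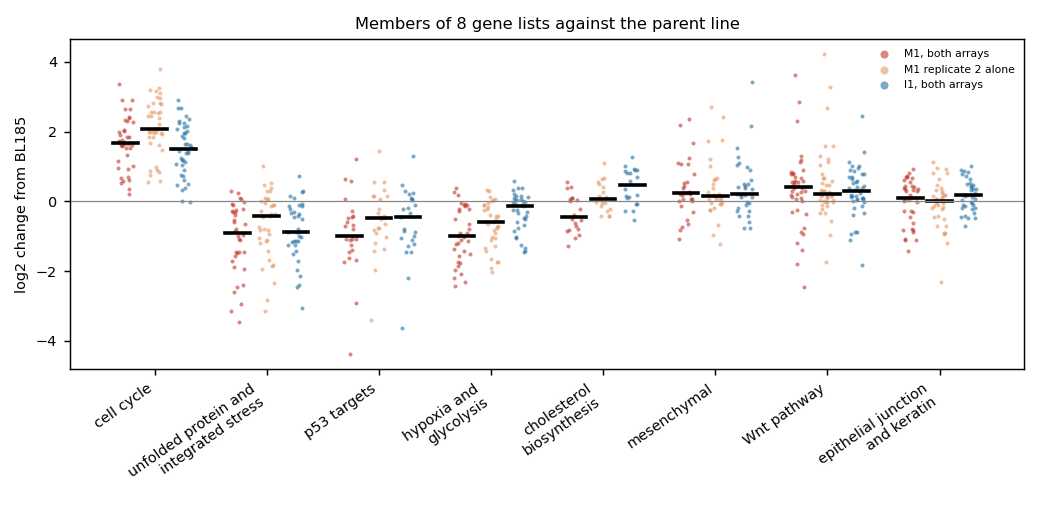
Log2 change from BL185 (vertical axis) of each measured member of 8 gene lists (horizontal axis), for M1 with both arrays, M1 replicate 2 alone and I1 with both arrays; points are genes and bars are list medians. The cell cycle medians were 1.67, 2.08 and 1.50, and the hypoxia and glycolysis medians were −0.99, −0.60 and −0.13.

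Between I1 and M1 directly, 0 genes passed an adjusted p of 0.05 by limma, and the smallest adjusted p was 0.0904. Of 18193 genes, 409 had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give. Small p-values were thus not in excess. The differences given here for single genes therefore did not pass. Those with the smallest p were, on the higher side in I1, Stmn2 (5.19 ± 0.29, SE), Slc39a4 (3.36 ± 0.23), the protease inhibitor Serpinb1a (3.06 ± 0.25), the prostaglandin-degrading enzyme Hpgd (2.97 ± 0.21), Krt14 (2.69 ± 0.23), Cyp4f14 (2.62 ± 0.20), Wfdc2 (2.47 ± 0.18) and Tlcd2 (1.98 ± 0.18). On the lower side were the membrane glycoprotein Pdpn (−2.28 ± 0.17), Wnt10a (−2.22 ± 0.41), the transcription factor Sox11 (−1.77 ± 0.30), the acetylcholine receptor subunit Chrna1 (−1.43 ± 0.19), Axin2 (−1.28 ± 0.28), Foxj1 (−1.03 ± 0.19), Prkd1 (−0.96 ± 0.18) and Spink4 (−0.90 ± 0.17). The sizes for Stmn2, Slc39a4, Hpgd and Cyp4f14, with M1 means of 7.22 to 7.87, and for Foxj1, Prkd1 and Spink4, with I1 means of 7.27 to 8.04, are not exact, as these means lay near or below the array medians. The count was 3746 without M1 replicate 1, of which 143 were higher and 226 lower in I1 by at least 2-fold, and 10365 without M1 replicate 2. Cyclic loess gave 52 calls and the 18S covariate 537.

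Camera called 9 lists between I1 and M1, with 0 members of any list called over all genes, and with an estimated correlation 0 of the 9 passed (adjusted p = 0.725 or higher). Hypoxia and glycolysis genes were higher in I1 (median 0.69, adjusted p = 1.54e-16; 33 of 35 members positive, and 1 called over the list alone), as were cholesterol biosynthesis genes (0.81, adjusted p = 2.5e-16; 20 of 20 positive), NRF2 and glutathione genes (0.41, 2.28e-08), fatty acid genes (0.26, 6.69e-05) and epithelial junction and keratin genes (0.11, 0.0179). Cell cycle genes were lower (−0.19, 0.00233). These 6 calls held without M1 replicate 1, where the medians were 0.25, 0.34, 0.09, 0.10, 0.14 and −0.57 in the same order. Leaving out M1 replicate 2 gave medians of 1.10 for hypoxia, 0.76 for NRF2 and 0.48 for fatty acid genes, and leaving out I1 replicate 1 gave −0.08 for cell cycle genes. Actin cytoskeleton genes (0.19, 0.0211), unfolded protein and stress response genes (0.19, 0.0119) and p53 targets (0.29, 0.00205) were higher in I1 with all arrays and had medians of −0.06, −0.20 and −0.08 without M1 replicate 1 (adjusted p = 0.463, 0.13 and 0.919), and of 0.43, 0.56 and 0.74 without M1 replicate 2. Stress response genes had a median of 0.33 without I1 replicate 1 and 0.11 without I1 replicate 2, which gave 0.11 for actin genes. Without M1 replicate 2 the epithelial and cell cycle lists no longer passed (adjusted p = 0.963 and 0.172, each with camera's direction turned), with medians of 0.16 and 0.26, and without I1 replicate 2 the actin and stress response lists no longer passed (0.0862 and 0.155).

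The remaining lists were not called between I1 and M1. The camera adjusted p was 0.0521 for integrins, 0.0534 for endothelial markers, 0.0645 for stellate markers and 0.0726 for collagens, 0.108 for Wnt and 0.109 for TGF-beta genes, and 0.18 for both proteases and imprinted genes. It was 0.234 for hepatocyte genes, 0.377 for Notch, 0.438 for macrophage markers, 0.519 for interferon and 0.56 for Hedgehog genes, 0.694 for chemokines, 0.769 for receptor tyrosine kinases, 0.781 for YAP targets, 0.783 for mesenchymal and 0.785 for fetal liver genes. Leaving out M1 replicate 1 brought 4 of these past the threshold, with camera adjusted p of 0.00248 for macrophage markers, 0.0113 for imprinted genes and 0.0383 for stellate markers, each higher in I1, and 0.0314 for YAP targets, lower in I1. In 13 of the 81 list tests the median, the mean and the direction of camera differed in sign. These were the fetal liver and Notch lists in M1 and I1 against BL185, the epithelial, protease and receptor tyrosine kinase lists in M1, the imprinted list in I1, and the chemokine, receptor tyrosine kinase, Hedgehog, Notch and YAP lists between I1 and M1. None of the 13 passed.

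Of 18 markers of epithelial, mesenchymal and liver identity fixed in advance, 17 were measured and 0 passed limma's threshold in either selected line with all arrays, with 4 in each at an unadjusted p under 0.05. Without M1 replicate 1, 4 passed in M1 (Cdh2, Snai2, Twist1 and Met) and 11 in I1, among them Cdh2 (adjusted p = 2.85e-06), Snai2 (8.68e-05), Mmp14 (0.000159), Snai1 (0.00033) and Afp (0.000573). Leaving out M1 replicate 2 gave 13 in M1 and 11 in I1. The mesenchymal cadherin Cdh2 differed by 1.25 ± 0.36 in M1 and 1.26 ± 0.36 in I1 (adjusted p = 0.225 and 0.266), and the transcription factor Snai1 by 1.10 ± 0.43 in both (0.321 and 0.418). With single arrays left out, the I1 change ran from 1.11 to 1.41 for Cdh2 and from 0.70 to 1.51 for Snai1. Snai2 differed by −0.73 ± 0.17 and −0.78 ± 0.17, Twist1 by 0.55 ± 0.17 and 0.40 ± 0.17, and Zeb1 by −0.32 ± 0.22 and −0.28 ± 0.22. The sizes for Twist1, with means of 6.53 to 7.08, and for Snai1, Alb, Afp and Mmp9, with BL185 means of 7.27 to 7.78, are not exact, with or without M1 replicate 1. The epithelial cadherin Cdh1 had means of 13.06 in BL185, 13.09 in M1 and 13.40 in I1, the intermediate filament gene Vim 14.76, 14.82 and 14.94, and the keratin Krt19 14.99, 14.68 and 15.06. Vim and Krt19 lay close to the top of the arrays, where differences are squeezed. Epcam differed by 0.39 ± 0.23 and 0.42 ± 0.23, and its other probe set by −1.70 and −0.71. The liver genes Alb (0.48 and 0.52), Afp (1.25 and 0.66) and Hnf4a (−0.52 and 0.31), and Igf2 (0.42 and 0.49), Cd44 (−0.31 and −0.10), Met (0.19 and −0.06), Mmp9 (0.49 and 0.34) and Mmp14 (0.25 and 0.70) also did not pass.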

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

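All tests of explanations in this part, and the bounds they were read against, were chosen after the results were seen and in part redrawn after their own values were seen, while the comparison of I1 with M1 by camera was planned.

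Between I1 and M1, camera found 9 lists whose changes differed between the selected lines. The adjusted p was 1.54e-16 for hypoxia and glycolysis genes, 2.5e-16 for cholesterol biosynthesis, 2.28e-08 for NRF2 and glutathione, 6.69e-05 for fatty acid metabolism, 0.00205 for p53 targets, 0.00233 for cell cycle genes, 0.0119 for the unfolded protein and stress response, 0.0179 for epithelial junction and keratin genes and 0.0211 for actin and motility genes. With an estimated correlation 0 of the 9 passed (smallest adjusted p = 0.725), and fry called 0. In data outside the gene tests, the 3′ 18S ribosomal RNA control probe set was higher than in BL185 by 1.47 in M1 and by 1.26 in I1 on the log2 scale. In M1 it read 12.50 on replicate 1 and 10.68 on replicate 2. The 5′ probe set read 10.16 on M1 replicate 1 but 8.82 on M1 replicate 2, below both BL185 arrays. In I1 it read 9.45 and 9.37, above both. The middle probe set was higher than in BL185 on every M1 and I1 array. The size of the M1 difference thus rests largely on replicate 1.

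M1 replicate 1 stood apart from M1 replicate 2. An unmixed BL185 array under the M1 label is argued against, since among genes that differ between M1 replicate 2 and BL185 by at least 1, 1.5 and 2 log2 units M1 replicate 1 lay nearer to M1 replicate 2 in 64.4%, 69.2% and 75.6%, against at most 0.2% for the BL185 arrays. An unmixed I1 array with the signal range of the other I1 arrays is argued against by 76.0% (19 of 25 genes) at 2 log2 units, where the I1 arrays gave at most 12.9%. The shares at 1 and 1.5 were however 27.4% and 52.6% (I1 arrays at most 11.4% and 7.1%), so at 1 most genes lay nearer to I1. Across probe sets M1 replicate 1 also correlated better with the I1 arrays (r = 0.948 and 0.943, against 0.994 between these) than with M1 replicate 2 (0.911). The reference arrays of both lines lacked the narrow range of M1 replicate 1, so a BL185 or I1 array with a compressed range was not tested. A compressed signal range is a candidate explanation: in the 3 brightest of 10 bins of parent signal minus the 3 dimmest, M1 replicate 1 minus replicate 2 was −1.31, against 0.05 for BL185 and −0.16 for I1 replicates. This value restates the narrow range already seen on that array, so it could hardly have come out otherwise. More fragmented RNA stays open, since the 3′ minus 5′ excesses of M1 replicate 1 over replicate 2, 0.198 for Actb (0.205 between BL185 replicates) and 0.209 for Gapdh (0.211 between I1 replicates), were no larger than elsewhere but come from 3′ probe sets 0.287 and 0.475 below the top of the array. The added poly-A controls read 1.48 on M1 replicate 1 and 2.75 on replicate 2 in this measure, so it does not read cell RNA alone. A mixture of lines, an outside sample and a true difference between M1 cultures were not tested.

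By camera at the preset correlation, cell cycle genes were higher and stress response genes lower in both selected lines, with 7 (M1) and 5 (I1) of 40 and 4 and 3 of 36 members called over all genes, and each call was lost with an estimated correlation (adjusted p = 0.725). Level-dependent compression of the arrays as the whole cause is argued against for both parts, since 0 of 10000 random lists matched on mean signal had a median as extreme, in M1 replicate 2 or in I1, for either list. The growth or nutrient state of the BL185 cultures at harvest may account for both parts as well as selection for migration: the changes of M1 replicate 2 and I1 correlated across members at 0.88 for cell cycle and 0.96 for stress response genes. A state of the parent cultures and a difference between lines would each give such a value, and the BL185 arrays are shared by both changes, so the explanations cannot be told apart here.

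For the 9 lists that differed between I1 and M1, the array M1 replicate 1 as the only source is argued against for 5, at the preset correlation alone: without it the adjusted p and the matched lists as extreme of 10000 were 1.42e-12 and 0 for cell cycle, 1.44e-06 and 0 for hypoxia, 0.000524 and 0 for cholesterol, 0.0383 and 2 for fatty acid and 0.047 and 0 for NRF2 genes. Between M1 replicate 1 and M1 replicate 2 these 5 lists had 261 to 2940 matched lists as extreme. For epithelial genes (0.00179 and 3) this source stays open. Their median between the M1 replicates was 0.047 against a matched −0.466, with 5 of 10000 as extreme. A count this small thus arose within a line and cannot decide. The hypoxia, cholesterol, fatty acid and NRF2 medians nonetheless shrank from 0.69, 0.81, 0.26 and 0.41 to 0.25, 0.34, 0.10 and 0.09, and without M1 replicate 2 the epithelial and cell cycle calls were lost (0.963 and 0.172), with the cell cycle median turned from −0.19 to 0.26. M1 replicate 1 is a candidate source for stress response (0.13, with 7982 matched lists as high) and p53 target genes (0.919, 1419) and stays open for actin genes (0.463, 315). With both M1 arrays, a comparison defined after those counts were seen, level-dependent compression of the arrays as the whole cause is argued against for 5 lists, with 0 of 10000 matched lists as extreme for cell cycle, hypoxia, cholesterol and NRF2 genes and 13 for fatty acid genes, is a candidate explanation for stress response genes (4126), and stays open for epithelial (843), actin (882) and p53 target genes (344). Culture conditions that differed between M1 and I1 were not tested and stay open beside a difference between the selected lines.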

How the results depend on the processing

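The tests with a minimum of 8, array weights, quantile normalization, the 18S covariate and crossed replicate numbers were chosen after the results were seen, and the others were planned. The planned minimum of 5 removed 0 genes and tests nothing. How many genes pass depended strongly on the setting and on the arrays kept, and the cause of a changed count was not tested unless it follows from fewer arrays. For lists only the 31 camera calls were followed: 383 of their results kept direction and side of the threshold, 133 lost the call, 62 of these in the estimated correlation and fry settings, and 11 reversed. After cyclic loess 9 of the 31 calls were lost and 1 reversed, and with the 18S covariate 6 were lost and 5 reversed. Quantile normalization lost 10, a minimum of 8 lost 10 and array weights lost 6. For named genes, 1716 stayed, 136 passed newly, 423 no longer passed and 31 reversed.

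For M1 minus BL185 (160 calls) the count was 338 with the mean of all probe sets, 1820 after cyclic loess, 241 after median centring, 312 with array weights, 1170 after quantile normalization, 2446 with the 18S covariate, 0 in a fit of 4 arrays, 5 at an adjusted p of 0.01 and 94 when adjusted over 3 contrasts. For I1 minus BL185 (93) it was 1582 after cyclic loess, 8551 with array weights, 980 after quantile normalization, 3963 with the 18S covariate, 8481 in a fit of 4 arrays, 3 at an adjusted p of 0.01 and 154 with every probe set. For I1 minus M1 (0) it was 52 after cyclic loess, 1 with a minimum of 8, 2 with array weights, 4 after quantile normalization, 537 with the 18S covariate and 13 when adjusted over 3 contrasts. The genes shared by M1 and I1 (69) numbered 1191 after cyclic loess, 112 after median centring, 303 with array weights, 735 after quantile normalization, 2113 with the 18S covariate, 0 in fits of 4 arrays, 3 at an adjusted p of 0.01 and 115 with every probe set. With each array left out in turn the counts ran from 0 to 12879 in M1, 0 to 8481 in I1, 0 to 10365 between I1 and M1 and 0 to 7136 shared, and r ran from 0.768 to 0.886. A correlation within 0.05 was taken as unmoved, a tolerance set after the data were seen.

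With the replicate number as a block the counts were 38 in M1, 1 in I1, 0 between I1 and M1, and 1 shared. Deviations of same-numbered arrays correlated at −0.131 for BL185 and M1, 0.161 for BL185 and I1 and 0.369 for M1 and I1, and nothing in the labels says that the numbers pair the arrays. With the BL185 numbers crossed, the M1 count was 76.

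Markers that did not pass changed sign as follows, the cause not tested. Only Afp with the 18S covariate then passed (limma adjusted p = 0.0053 in I1 and 0.0297 in M1). In I1 the 18S covariate gave Afp −1.22, Alb −0.011, Cd44 0.18, Igf2 −0.11, Met 0.48, Mmp9 −0.35 and Zeb1 0.041, and the probe set mean gave Epcam −0.15 and Hnf4a −0.015. Met in I1 was 0.10 after cyclic loess and 0.14 after quantile normalization. In M1 the 18S covariate gave Afp −0.94, Alb −0.14, Cd44 0.02, Hnf4a 0.10, Igf2 −0.28, Mmp9 −0.32 and Zeb1 0.048. The probe set mean gave Epcam −0.66, Mmp14 −0.17 and Zeb1 0.029, and Zeb1 was 0.17 after cyclic loess and 0.13 after quantile normalization. With arrays left out, Met in I1 ran from −0.22 to 0.10, and in M1 Afp ran from −0.12 to 2.63, Cdh1 from −0.30 to 0.37, Igf2 from −0.015 to 0.86, Met from −0.22 to 0.61, Mmp9 from −0.012 to 0.99 and Vim from −0.10 to 0.21.

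Camera turned direction with the 18S covariate for hepatocyte (adjusted p = 0.711), NRF2 (0.816), stellate (0.294) and endothelial genes (0.808) in M1 and for hypoxia genes in I1 (0.858), and after cyclic loess for stress response genes between I1 and M1 (0.84). Between I1 and M1, with arrays left out, camera's adjusted p ran from 0.00179 to 0.963 for epithelial, 0.00744 to 0.463 for actin, 1.42e-12 to 0.172 for cell cycle, 0.00106 to 0.155 for stress response and 0.00172 to 0.919 for p53 target genes, with camera's direction turned without M1 replicate 2 for epithelial and cell cycle genes and without M1 replicate 1 for the others.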

Other observations

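The genes in this part were chosen after their values were seen, and the descriptions carry no test of an explanation.

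Of 16 measured host genes of small nucleolar RNAs (the Snhg genes, Gas5 and Zfas1), a class on none of the fixed lists, 3 were called lower in M1 and 2 in I1. A negative change, called or not, was seen in 81.2% of them in each line, against 52.7% in M1 and 48.5% in I1 of other genes of like signal, and the group was not tested as a list. By limma, Snhg12 (−2.82 ± 0.17, SE), Snhg16 (−2.67 ± 0.19) and Zfas1 (−1.61 ± 0.18) fell in M1, and Snhg12 (−2.80 ± 0.17) and Snhg16 (−2.50 ± 0.19) fell in I1, with 0 called higher. The Snhg12 means of 7.45 in M1 and 7.47 in I1 lay below the array medians, so its sizes are not exact. Gas5 (−1.92 and −1.65), Snhg1 (−1.42 and −2.10) and Snhg5 (−2.03 and −2.02) did not pass in M1 or I1. With M1 replicate 1 left out, 10 of the 16 were called lower and 2 higher in M1, where the median was −0.83, and 12 lower and 2 higher in I1.

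Several large differences fell short of the threshold where the M1 arrays disagreed. The p53 and stress target Gadd45a had a mean log2 signal of 12.98 ± 0.13 in BL185, 8.60 ± 1.38 in M1 and 9.35 ± 0.19 in I1 (SD, n = 2), with limma adjusted p of 0.0609 and 0.109. The neutrophil-attracting chemokine Cxcl5 had means of 6.60 ± 0.02, 10.29 ± 1.36 and 11.02 ± 0.33 (SD, n = 2), with limma adjusted p of 0.0822 and 0.0766. Its BL185 mean lay below the array medians, so the sizes of its differences are not exact. With M1 replicate 1 left out M1 is a single array, and a test then leaves out the spread between the M1 arrays that these genes were picked for.

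The Mycn difference rested on 1 probe set. It read 15.39 ± 0.04 in BL185, where it was the highest value of both arrays, so that the difference is not exact, 11.18 ± 0.03 in M1 and 10.94 ± 0.14 in I1, in means ± SD (n = 2). The other probe sets of Mycn, at 7.44, 8.14 and 8.09 and at 8.04, 7.96 and 7.94 in the same order of lines, lay near the array medians. They did not show the high BL185 signal of the first. Which of the probe sets reads the Mycn transcript was not tested, so a fall of Mycn itself is not established.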
